A study of Homo sapiens with 6 samples.

How the data were processed

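Gene expression was measured in U937, an established human myelomonocytic cell line, on 6 one-colour Agilent arrays, 1 array per sample. In 3 samples the cells had been induced to express wild-type c-Kit and were stimulated with 100 ng/ml of its ligand, stem cell factor (SCF), for 24 hours in medium without serum, per the labels' protocols. In the other 3 samples the cells had been induced to express D816V c-Kit, the active mutant with a substitution at codon 816. The labels do not state SCF or serum starvation for the D816V samples, so the mutation, SCF and the serum condition cannot be told apart in these data. The labels call the samples replicates without naming separate cultures, so p-values measure only the spread between these samples, which may be technical.

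The deposited files are scanner output of Agilent Feature Extraction version 10.5.1.1, per the file headers, and hold the brightness (intensity) of each spot on a linear scale. The processed signal had been background-subtracted and detrended within each array and was not normalized between arrays, per the file headers. The deposited mean signal and median local background intensity of each spot were used only for the alternative background correction. Flags of 0 or 1 for spots well above background, saturated spots and outlier spots were taken as deposited. The extraction protocol in the labels names another array manufacturer, and the file headers were followed here.

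Each array held 51538 non-control spots of 50238 distinct probes. Control spots and the 53 to 115 outlier-flagged spots per array were left out, and spots of 1 probe were averaged on the log2 scale. The log2 processed signal minus the 75th percentile of its array was analysed, so all levels below are log2 values relative to that percentile. Probes were named through a table of RefSeq accessions and symbols of assembly GRCh38.p14, used for names only: 28595 probes matched by their main accession, 338 by another RefSeq accession and 3869 by a current or unique older symbol. The other 17436 probes kept the name in the files. The files give no mapped position for the probes, and no genome was used here, so no coordinates are given.

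Each gene was represented by the probe of highest mean signal over all arrays among probes with a value on all 6 arrays, and 226 probes with an outlier flag on an array were not eligible. A gene was tested when this probe was well above background on all 3 arrays of at least 1 group, which left 16046 genes or transcripts, of which 11607 had a reference symbol. Between 45.1% and 55.3% of spots per array were well above background. For arrays, precision is limited by the number of arrays, 3 per group.

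The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Log2 fold changes are D816V minus wild type, with the moderated standard error (SE). Saturated spots were kept at their value, and 278 tested genes were saturated on at least 1 array, 139 of them on all 6. No fold is given for a named gene that was saturated on arrays of both groups. A gene not well above background on any array of a group has only a bound there: the fold is given as "at least", from the mean of the brighter group and the mean of the dimmer group with each array at the higher of its lowest signal well above background and the probe's own signal. Such a bound concerns the measured means and the detection limit. It leaves out the spread between arrays, so it is not a confidence limit. The bound is also for the main processing only, and the range of log2 fold changes under the alternatives is given beside it. Of 26 gene lists fixed before the data were examined, 25 had at least 2 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. The list of genes that the study measured by quantitative PCR was chosen by the study on these samples.

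The genes named were fixed by a rule before the data were examined: KIT; the 4 genes measured by quantitative PCR; up to 12 genes per direction past the threshold or, as happened, the 5 of smallest p in each direction, which did not pass; and, from each list without a member past the threshold, the 2 tested members of largest absolute log2 fold change. Genes named outside this rule are said to be so, and 1 gene that the rule names is not reported here.

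On simulated data with the means and spreads of this comparison over 16046 genes, 87 of 100 genes changed by 2 on the log2 scale passed the threshold and 10 of 100 genes changed by 1 did, with 4 unchanged genes called. The simulation drew independent noise for each gene and array from limma's moderated spreads. In the real data genes deviated together, with an estimated correlation of 0.88 in the interferon list. The simulated shares come from a single draw and may not hold for these data, and the direction of the difference was not tested. Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a filter on all 6 arrays, all probes of a gene, the slide as a block, a replicate block, trend and robust variance, array weights, an estimated correlation for lists, and leaving out each array. Scaling over probes above background on all 6 arrays, leaving out a pair of arrays, removing probes with repeat runs, and removing genes saturated on any array were added after seeing the data. One wild-type array (replicate 1) was alone on its slide, and the other 5 arrays shared a slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.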

Results

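The data comprised 6 arrays of total RNA from U937 cells: 3 of cells expressing wild-type c-Kit under SCF for 24 hours and 3 of cells expressing D816V c-Kit. c-Kit is the receptor tyrosine kinase for SCF, and the D816V mutant is active without ligand. The comparison asked how gene expression differs between cells carrying the mutant receptor and cells in which the normal receptor was stimulated. The median processed signal per array ran from 14.9 to 23.6 and the 75th percentile from 143 to 186.

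KIT was well above background on all 6 arrays, and its difference between the groups did not pass the threshold. Its single probe (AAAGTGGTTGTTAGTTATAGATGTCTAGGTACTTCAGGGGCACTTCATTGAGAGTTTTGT) read 2.34 ± 0.45 (SD, n = 3) with wild-type c-Kit and 2.65 ± 0.88 (SD, n = 3) with D816V c-Kit, a log2 fold change of 0.31 (SE 0.46, limma adjusted p = 1.0). The wild-type arrays read 2.83, 1.95 and 2.25, and the D816V arrays 3.11, 3.21 and 1.64. The probe's position relative to the introduced sequence was not determined here, so these values do not show how much of the introduced receptor was expressed, or which form. KITLG, the gene of SCF, was not well above background on any array with any of its 3 probes.

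No gene passed the threshold in either direction: limma called 0 of 16046 genes, with a smallest adjusted p of 0.233, and 623 genes (3.88%) had an unadjusted p under 0.05, where chance gives 802.3. Of these 623 genes, 204 had a positive and 419 a negative log2 fold change. Dim genes read lower with D816V c-Kit, with a median of -0.24 in the lowest of 10 bins of signal. Of all tested genes, 138 were not well above background on any D816V array, against 8 on any wild-type array. Whether this accounts for the excess of negative values was not tested. The groups did not overlap for 1578 genes, or 9.83%, where chance gives 10% for 3 against 3. An absolute log2 fold change of at least 1 was measured for 342 genes, 190 positive and 152 negative. Of the 190, 52 were read by a probe with a run of 8 or more bases of alternating G and A, against 84 of all 16046 genes. Without D816V replicate 3 the count of called genes was 7, and all 7 were read by such probes. Without wild-type replicate 1 and D816V replicate 3 together, an alternative chosen after seeing the data, it was 70, of which 41 were read by such probes.

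Of the 4 genes that the study measured by quantitative PCR, none passed over all genes and 2 passed adjusted over the list alone, PIK3CB and MOAP1. The study chose this list on these samples, so the latter count is not independent evidence. PIK3CB, a catalytic subunit of phosphoinositide 3-kinase, read -3.30 ± 0.34 (SD, n = 3) with wild-type and -2.58 ± 0.15 (SD, n = 3) with D816V c-Kit, a log2 fold change of 0.73 (SE 0.23), and was well above background on 1 of the 3 wild-type arrays. MOAP1, a modulator of apoptosis, read -1.85 ± 0.74 (SD, n = 3) with wild-type c-Kit and was not well above background on any D816V array. This puts its wild-type mean at least 2.19-fold higher in the main processing, a bound that leaves out the spread between arrays. Under the alternatives the log2 fold change of MOAP1 ran from -1.64 to -0.37, so the bound did not hold under all of them. EIF4B, a translation initiation factor, had a log2 fold change of 0.52 (SE 0.27) at its brightest probe, and its 5 probes ranged from 0.09 to 1.01. The value of 1.01 came from the EIF4B probe with a run of 9 alternating G and A. CAVIN3, named PRKCDBP in the files and encoding a protein of caveolae, had a log2 fold change of 0.10 (SE 0.33), and its 2 probes disagreed, the other at -1.07.

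**Figure D1:**
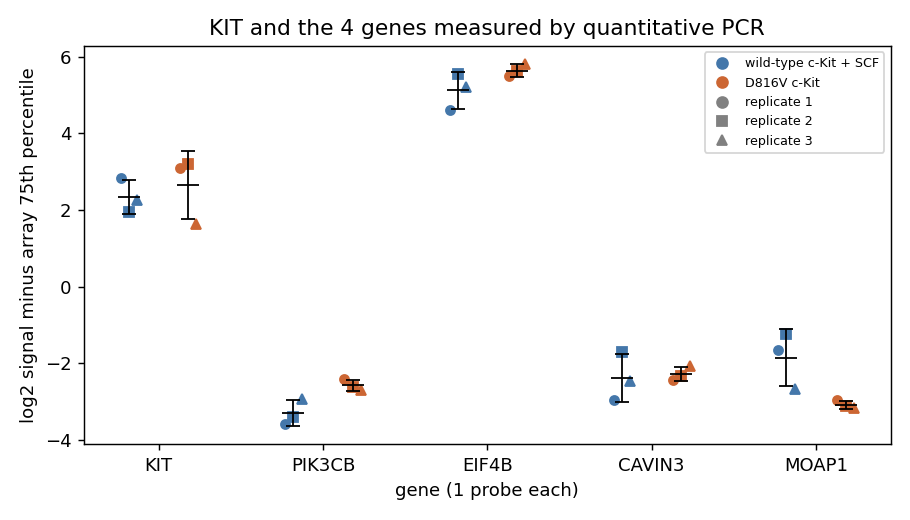
Log2 signal minus the array's 75th percentile (vertical axis) for KIT and the 4 genes measured by quantitative PCR (horizontal axis), with 1 point per array, horizontal ticks for group means and bars for the SD of 3 arrays. KIT overlapped between the groups and PIK3CB did not, with a log2 fold change of 0.73 that did not pass the threshold over all genes. The D816V points of MOAP1 and the points of 2 of the 3 wild-type arrays for PIK3CB were not well above background.

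The genes of smallest p did not pass. With positive log2 fold changes these were CFC1 (2.01, SE 0.41), CLK1, a kinase of splicing factors (0.80, SE 0.17), LIG3, a DNA ligase (0.92, SE 0.20), CENPT, a centromere protein (1.06, SE 0.23), and U2AF2, a splicing factor (1.08, SE 0.25). With negative values, APOBEC3C, a cytidine deaminase, had -1.55 (SE 0.24) and KRTAP11-1, a keratin-associated protein, -1.55 (SE 0.24). KCNAB1, a potassium channel subunit, and the small nuclear RNA RNU12 were not well above background on any D816V array. This puts their wild-type means at least 1.75-fold and at least 1.57-fold higher in the main processing. These bounds did not hold under all alternatives, where log2 fold changes ran from -1.73 to -0.30 for KCNAB1 and from -1.38 to -0.24 for RNU12. DUX4L8 had the smallest p and was not well above background on any D816V array, and its wild-type level was too low to give a bound.

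Among the fixed gene lists, genes of cholesterol and fatty acid synthesis passed camera as higher on the D816V arrays, with the preset correlation only. Of 25 tested members 23 had a positive log2 fold change, with a mean of 0.37 (camera adjusted p = 3.2e-09, and adjusted p = 0.72 with an estimated correlation), while none passed singly over all genes or adjusted over the list alone. The list stood at 0.19 ± 0.12 (SD, n = 3) on the D816V arrays and at -0.19 ± 0.15 (SD, n = 3) on the wild-type arrays, relative to each gene's mean. SCD, the desaturase that makes oleate, had a log2 fold change of 0.92 (SE 0.26). Within the slide of 5 arrays the mean was also 0.37 (camera adjusted p = 4.6e-10, and adjusted p = 0.74 with an estimated correlation).

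Ribosomal protein genes also passed camera, with a mean of 0.13 and 64 of 74 positive (adjusted p = 3.5e-07, and adjusted p = 0.72 with an estimated correlation), but 56 of the 74 were saturated on at least 1 array. The 18 that were saturated on no array, an alternative chosen after seeing the data, had a mean of -0.01 with 10 positive (adjusted p = 0.88). Within the slide of 5 arrays the mean of all 74 was 0.16 (adjusted p = 1.1e-10, and adjusted p = 0.78 with an estimated correlation). RPS27 and RPL7 were saturated on all 3 D816V arrays and on 2 of the 3 wild-type arrays, so no fold is given. After quantile normalization the mean was -0.04 (adjusted p = 0.56), and median log2 fold change of all genes ran from -0.24 in the lowest of 10 bins of signal to 0.07 in the highest. Genes of heat shock and oxidative stress also passed camera, with a mean of 0.33 and 22 of 25 positive (adjusted p = 1.2e-04). With an estimated correlation the adjusted p was 0.72. Within the slide of 5 arrays the mean was 0.48 (adjusted p = 4.2e-09, and adjusted p = 0.74 with an estimated correlation). FTH1, the ferritin heavy chain, had a log2 fold change of 1.24 (SE 0.45). It read 6.86, 7.01 and 5.47 on the D816V arrays and 4.69, 5.62 and 5.32 on the wild-type arrays. HMOX1, heme oxygenase, had 1.44 (SE 1.35) and read 4.48 and 4.63 on D816V arrays 1 and 2 but 0.11 on D816V array 3. The wild-type arrays were uneven for HMOX1 too, at 3.61, 0.50 and 0.80. The heat shock list stood at 0.13, -0.60 and -0.03 on the wild-type arrays and at 0.09, 0.16 and 0.25 on the D816V arrays. Without wild-type replicate 2 this list had a mean log2 fold change of 0.12 (adjusted p = 0.27).

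MHC class II and antigen presentation genes passed camera as lower, with a mean of -0.38 and 12 of 13 negative (adjusted p = 2.3e-03). With an estimated correlation the adjusted p was 0.72. CIITA, the transactivator of class II genes, had a log2 fold change of -0.90 (SE 0.43), and TAP2, a peptide transporter, -0.77 (SE 0.25). The list stood 0.59 above its mean on wild-type array 1 and at -0.49 on D816V array 3. The other arrays lay between -0.05 and 0.01, so the difference came from these arrays. Within the slide of 5 arrays, without wild-type array 1, the mean log2 fold change of the list was -0.18 (adjusted p = 0.13). Without D816V replicate 3 it was -0.22 (adjusted p = 0.25), and without both of these arrays -0.03 (adjusted p = 0.94). With array weights on all 6 arrays it was -0.14 (adjusted p = 0.28). With fry none of these 4 lists passed (adjusted p = 0.32 for cholesterol synthesis and for ribosomal proteins, 0.92 for heat shock and 0.86 for MHC class II).

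Interferon-stimulated genes did not pass in the main setting over all 6 arrays, with a mean log2 fold change of -0.13 and 6 of 27 positive (adjusted p = 0.54). Wild-type array 1, alone on its slide, stood 2.44 above the genes' mean, D816V arrays 1 and 2 at 0.57 and 0.55, and the other 3 arrays at -1.001, -1.25 and -1.31. Within the slide of 5 arrays the mean log2 fold change was 1.06 with 26 of 27 positive (camera adjusted p = 2.6e-11, and adjusted p = 0.78 with an estimated correlation). IFITM1, an interferon-induced membrane protein, read 4.25 on wild-type array 1 and -4.64 and -3.33 on the other wild-type arrays, and IFI35 read 1.90, -1.38 and -1.26. NF-kB and inflammatory genes had a mean of -0.46 with 4 of 24 positive (adjusted p = 0.17), and 0.30 within the slide (adjusted p = 8.4e-05, and adjusted p = 0.78 with an estimated correlation). TNF read 6.98 on wild-type array 1 and between 1.57 and 3.07 on the other 5 arrays, and CXCL2 read 3.77 there and between -1.03 and 0.08 on the others. With median scaling of all 6 arrays both lists passed as lower than other genes, with means of 0.08 for interferon (adjusted p = 0.027) and -0.26 for NF-kB (adjusted p = 0.0022) where the median of all genes was 0.18, and adjusted p = 0.98 for both with an estimated correlation. With array weights on all 6 arrays the interferon list passed as higher instead, with a mean of 1.03 (camera adjusted p = 9.8e-05, and adjusted p = 0.66 with an estimated correlation). Without wild-type replicate 2 the interferon mean was -0.66 (adjusted p = 0.036), and without wild-type replicate 3 the means were -0.78 (adjusted p = 0.0068) and -1.01 for NF-kB (adjusted p = 6.8e-06). Without D816V replicate 2 the NF-kB mean was -0.58 (adjusted p = 0.032), and none of these calls held with an estimated correlation (adjusted p = 0.73 to 0.96).

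**Figure D2:**
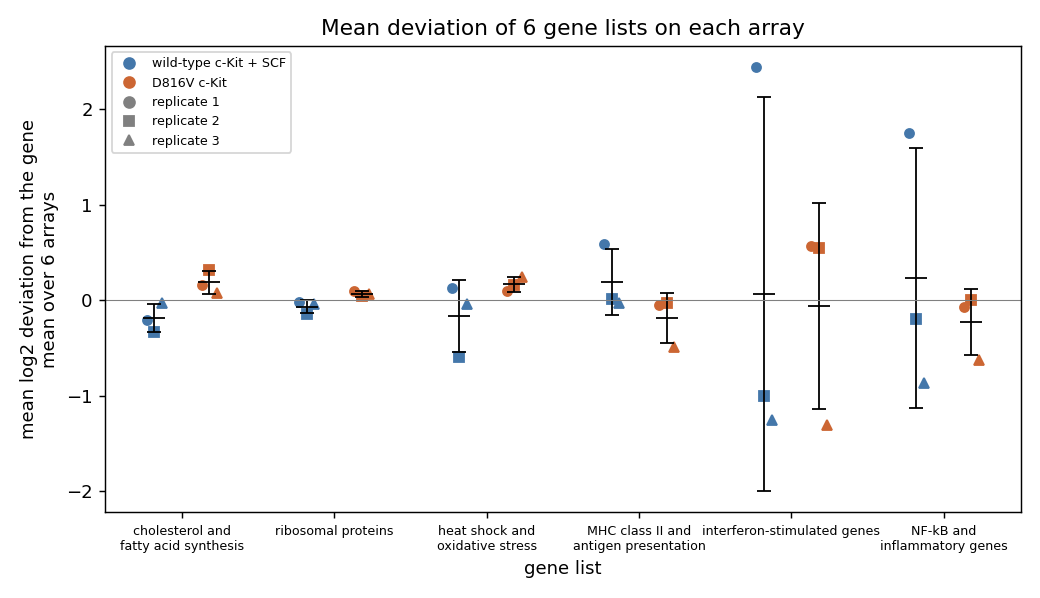
Mean log2 deviation of list members from each gene's mean over 6 arrays (vertical axis) for 6 gene lists (horizontal axis), with 1 point per array, horizontal ticks for group means and bars for the SD of 3 arrays. Of the 74 ribosomal protein genes, 56 were saturated on at least 1 array. Cholesterol synthesis genes stood higher on the D816V arrays by 0.37, and interferon-stimulated and NF-kB genes stood 2.44 and 1.76 above their mean on wild-type array 1.

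The signalling lists closest to the receptor did not pass. Among ERK pathway feedback and output genes 9 of 19 were positive (adjusted p = 0.98); IER3, an immediate early gene, had -1.02 (SE 1.33) and ETV4 -0.90 (SE 0.46). Among STAT5 and cytokine target genes 5 of 12 were positive (adjusted p = 0.96), with SOCS1, a cytokine signalling inhibitor, at -0.79 (SE 0.37) and CISH, another, at 0.75 (SE 0.39). CISH read 4.31, 4.52 and 3.01 on the D816V arrays and 3.15, 3.29 and 3.15 on the wild-type arrays. Components of the PI3K, AKT and mTOR pathway had 14 of 25 positive (adjusted p = 0.35). PIK3R5 had 1.73 (SE 0.98) at a probe with a run of 9 alternating G and A, and -0.40 when such probes were removed, and PIK3R3 had 0.98 (SE 0.39). Components of the RAS, RAF and MAPK pathway had 7 of 23 positive (adjusted p = 0.18), with the kinases ARAF at -0.87 (SE 0.32) and MAPK3 at -0.74 (SE 0.25). The quantitative PCR genes as a list had an adjusted p of 0.42, and their mean was 0.03.

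Lists of growth and survival did not pass in the main setting over all 6 arrays either. Translation initiation factors had 13 of 38 positive (adjusted p = 0.71), with EIF4A2 at 0.42 (SE 0.20). Apoptosis regulators had 19 of 31 positive (adjusted p = 0.66), with the initiator caspase CASP8 at 0.85 (SE 0.89). CASP8 read 3.19 on wild-type array 1 and between 5.96 and 6.86 on the other arrays. Cell cycle and DNA replication genes had 14 of 44 positive (adjusted p = 0.54), with the proliferation marker MKI67 at -0.67 (SE 0.22) and the mitotic kinase AURKB at -0.48 (SE 0.18). Quiescence and FOXO target genes had 9 of 14 positive (adjusted p = 0.40), with GADD45B at 0.63 (SE 0.26) and KLF6 at -0.61 (SE 0.68). Replication-dependent histones had 27 of 39 positive (adjusted p = 0.077), with H3C11 at 0.71 (SE 0.46) and H1-5 at 0.53 (SE 0.28); within the slide their mean was 0.16 (adjusted p = 9.6e-05, and adjusted p = 0.78 with an estimated correlation). Leaving out single arrays brought some of these lists past the threshold, none of them with an estimated correlation (adjusted p = 0.73 to 0.97). Without D816V replicate 3 translation initiation factors had a mean of -0.18 (adjusted p = 0.019), cell cycle genes -0.23 (adjusted p = 0.0096) and quiescence genes 0.46 (adjusted p = 0.0032). Cell cycle genes also had -0.23 without wild-type replicate 2 (adjusted p = 0.0042). Histones had 0.16 without wild-type replicate 3 (adjusted p = 0.013), 0.12 without D816V replicate 1 (adjusted p = 0.042) and 0.18 without D816V replicate 2 (adjusted p = 6.7e-04). Array weights on all 6 arrays brought past the threshold translation initiation factors (-0.19, camera adjusted p = 0.0091), cell cycle genes (-0.23, camera adjusted p = 0.0024) and quiescence genes (0.47, camera adjusted p = 0.0030). With an estimated correlation these had adjusted p = 0.64 to 0.70.

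The other metabolic and stress lists did not pass in the main setting over all 6 arrays. Hypoxia and glycolysis genes had 11 of 26 positive (adjusted p = 0.98), with a mean of 0.03 and a median of -0.08; PFKL had 1.60 (SE 1.44) and read 1.20 on wild-type array 1 against 6.01 to 7.07 on the others, and ALDOA was saturated on all 3 D816V arrays and on 2 of the 3 wild-type arrays, so no fold is given. Oxidative phosphorylation genes had 13 of 44 positive (adjusted p = 0.54), with CYC1 at -0.36 (SE 0.19) and COX7B at -0.30 (SE 0.36). Genes of the unfolded protein and integrated stress response had 17 of 27 positive (adjusted p = 0.20), with SLC7A11 at -0.46 (SE 0.24) and DNAJB9 at 0.44 (SE 0.41). Without wild-type replicate 2 oxidative phosphorylation genes had a mean of -0.24 (adjusted p = 3.8e-04) and unfolded protein response genes 0.21 (adjusted p = 0.0043), and without D816V replicate 3 the latter had 0.23 (adjusted p = 0.0058). Neither list passed there with an estimated correlation (adjusted p = 0.83 and 0.73). On all 6 arrays, oxidative phosphorylation genes passed with normexp (-0.11, camera adjusted p = 0.031) and with array weights (-0.18, camera adjusted p = 0.0094). Unfolded protein response genes passed with array weights (0.23, camera adjusted p = 0.0022). With an estimated correlation these had adjusted p = 0.64 to 0.81.

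Markers of blood cell types did not pass in the main setting over all 6 arrays. Monocyte and macrophage markers had 13 of 21 positive (adjusted p = 0.34), and within the slide a mean of 0.53 (adjusted p = 2.4e-04, and adjusted p = 0.78 with an estimated correlation). D816V arrays 1 and 2 stood at 0.39 and 0.42 for this list, D816V array 3 at -0.49, and wild-type arrays 2 and 3 at -0.33 and -0.51. Without D816V replicate 3 the mean was 0.52 (adjusted p = 0.0048, and adjusted p = 0.76 with an estimated correlation), and without wild-type replicate 1 as well it was 0.83 (adjusted p = 6.2e-08, and adjusted p = 0.38 with an estimated correlation). CD86, a costimulatory molecule, had 1.64 (SE 0.93) at a probe with a run of 12 alternating G and A, and S100A8 had 1.17 (SE 0.61). Mast cell and basophil markers had 6 of 7 positive (adjusted p = 0.081), with the tryptase TPSB2 at 0.47 (SE 0.34) and MS4A2 at 0.35 (SE 0.26); within the slide their mean was 0.18 (adjusted p = 0.045, and adjusted p = 0.78 with an estimated correlation), and without D816V replicate 3 it was 0.33 (adjusted p = 0.0096, and adjusted p = 0.73 with an estimated correlation). Granulocyte and myeloid progenitor markers had 6 of 13 positive (adjusted p = 0.51), with a mean of 0.06, and of -0.02 over the 11 saturated on no array; CEBPA was saturated on 2 of the 3 arrays of each group, so no fold is given, and RNASE2 had -0.26 (SE 0.60). Lymphoid markers had 2 of 9 positive (adjusted p = 0.17), with VPREB3 at -0.80 (SE 0.31) and CD7 at -0.60 (SE 0.27). Erythroid and megakaryocyte markers had 3 of 9 positive (adjusted p = 0.34), with HBA2 at -0.95 (SE 0.48) and GP1BA at -0.56 (SE 0.49). Epithelial and fibroblast markers had 6 of 10 positive (adjusted p = 0.65), with PDGFRA at 1.30 (SE 0.75). PDGFRA read -4.63, -1.88 and -1.64 on the wild-type arrays and -1.30, -1.31 and -1.63 on the D816V arrays, so its value rested mainly on wild-type array 1. KRT19 was not well above background on any D816V array, which puts its wild-type mean at least 1.26-fold higher in the main processing. Under the alternatives its log2 fold change ran from -0.91 to -0.08, so the bound did not hold under all of them. Without wild-type replicate 3 granulocyte markers had a mean of 0.28 (adjusted p = 0.019) and lymphoid markers -0.34 (adjusted p = 0.027), and without D816V replicate 1 the latter had -0.38 (adjusted p = 0.017). With no filter on dim probes erythroid markers had -0.54 (adjusted p = 0.0030), and none of these calls held with an estimated correlation (adjusted p = 0.73 to 0.85). Array weights on all 6 arrays brought past the threshold monocyte markers (0.65, camera adjusted p = 6.5e-05) and mast cell markers (0.29, camera adjusted p = 0.0091). Each had an adjusted p of 0.64 with an estimated correlation.

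Some named genes were well above background on only part of a group's arrays. With wild-type c-Kit these were PIK3CB, CFC1 and IFITM1 on 1 of 3 arrays and PIK3R3 and PDGFRA on 2 of 3. With D816V c-Kit they were ETV4, MKI67 and HBA2 on 1 of 3 and KRTAP11-1, ARAF and GP1BA on 2 of 3.

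The arrays did not group by receptor. D816V arrays 1 and 2 correlated most closely across genes (Pearson r = 0.992), and each correlated with D816V array 3 at 0.968. Wild-type array 3 correlated with D816V array 3 at 0.985 and with wild-type array 2 at 0.985. Wild-type array 1 correlated with the other arrays at 0.955 to 0.960. Genes are not independent replicates, so these values describe the arrays only.

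**Figure D3:**
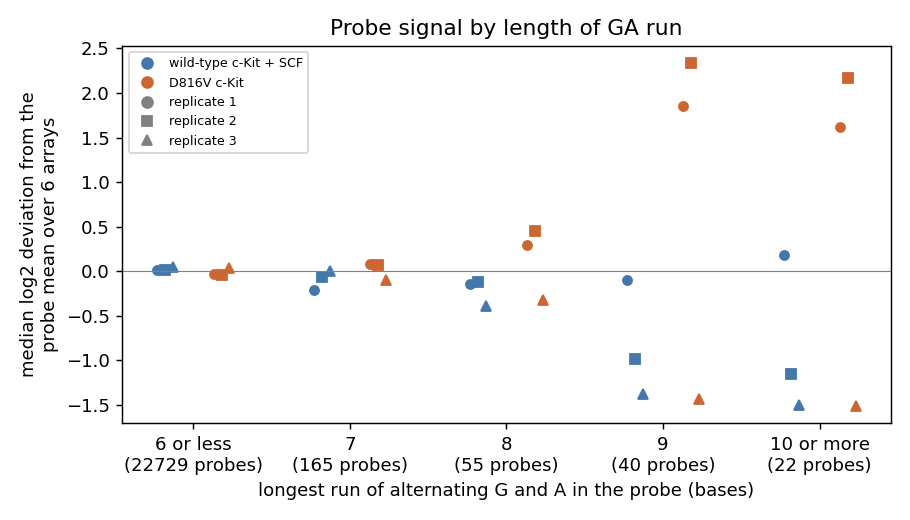
Median log2 deviation from the probe mean over 6 arrays (vertical axis) by the longest run of alternating G and A in the probe, in bases (horizontal axis), with 1 point per array. For runs of 9 bases D816V arrays 1 and 2 stood at 1.86 and 2.34, and D816V array 3 at -1.44.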

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

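The tests that scaled over probes above background on all 6 arrays, left out a pair of arrays, or removed repeat-run probes or saturated genes were chosen only after the result was seen. The count of 0 genes changed was kept under every alternative except 2 that left out arrays: leaving out each array in turn gave 0 to 7 genes changed, 0 to 7 higher, 0 lower and 0 to 7 changed at least 2-fold, with 7 without D816V replicate 3, and leaving out wild-type 1 and D816V 3 together gave 70 genes changed, 69 higher, 1 lower and 70 changed at least 2-fold. The number of genes at unadjusted p under 0.05 ran from 297 without D816V replicate 2 to 1515 with array weights. KIT stayed positive and short of the threshold under all 20 alternatives (0.03 to 1.06, adjusted p 0.23 to 1.0). The number of lists past the threshold, 4, became 0 with the correlation estimated per list, 8 with the slide as a block, 11 with array weights, 6 to 9 leaving out each array in turn (7 without wild-type replicate 2, 8 without wild-type replicate 1, 9 without wild-type replicate 3 and 9 without D816V replicate 3), and 10 with both arrays left out; the cause was not tested. Same-numbered arrays deviated from their group means with r = -0.11, 0.19 and 0.29. With 3 arrays per group these values neither show nor exclude that the numbers pair the samples. With the replicate block 0 genes and 4 lists passed, and 781 genes had an unadjusted p under 0.05.

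Of 25 lists tested, 17 passed in the main setting or an alternative, and none of these 120 calls held with an estimated correlation (adjusted p = 0.27 to 0.98). On simulated data with independent noise, a shift of 0.5 was given to the cholesterol list. It reached camera adjusted p = 5.4e-12 with the preset correlation and 0.049 with an estimated one. The lists past the threshold in the main setting had smaller mean shifts, so missing it with an estimated correlation does not show that they did not shift. With array weights, translation initiation factors (-0.19), cell cycle (-0.23), oxidative phosphorylation (-0.18), quiescence (0.47), monocyte (0.65), mast cell (0.29) and unfolded protein response (0.23) lists passed, and MHC class II no longer did (-0.14). With normexp, oxidative phosphorylation passed (-0.11). With both arrays left out, translation initiation factors (-0.17), quiescence (0.43), monocyte (0.83), mast cell (0.31) and unfolded protein response (0.16) lists passed.

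Among named genes, DUX4L8, PIK3R5, CD86, IFITM1 and HMOX1 passed the threshold with both arrays left out, and no named gene passed under another alternative. Of 500 list means under alternatives, 66 had the other sign and passed in neither setting. Signal over background limits the dim genes: 138 tested genes were not well above background on any D816V array, and 8 on any wild-type array.

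Values of the opposite sign follow, none past the threshold for single genes. With the slide as a block, which equals leaving out wild-type replicate 1, CAVIN3 was -0.20, CASP8 -0.27, KLF6 0.11, RNASE2 0.19, IFI35 0.20, PFKL -0.27, the interferon list 1.06 and the NF-kB list 0.30. With array weights CAVIN3 was -0.050, IER3 0.87, KLF6 0.19 and the interferon list 1.03 (adjusted p = 9.8e-05). With both arrays left out CAVIN3 was -0.30, IER3 1.24, CASP8 -0.14, KLF6 0.60, IFI35 0.55, PFKL -0.0016, GP1BA 0.24, the interferon list 1.69 and the NF-kB list 0.50. Without D816V replicate 3 CAVIN3 was -0.0085 and IER3 0.36; without wild-type replicate 2 IFITM1 was -0.59; without wild-type replicate 3 RNASE2 was 0.018. Leaving out each array in turn gave -0.20 to 0.43 for CAVIN3, -2.01 to 0.36 for IER3, -0.27 to 1.48 for CASP8, -1.02 to 0.11 for KLF6, -0.98 to 0.19 for RNASE2, -0.59 to 3.85 for IFITM1, -1.44 to 0.20 for IFI35, -0.27 to 2.59 for PFKL, -0.78 to 1.06 for the interferon list and -1.01 to 0.30 for the NF-kB list. The 3.85 for IFITM1 was without wild-type replicate 1. The wild-type arrays left were not well above background for this gene, so 3.85 is not a measured size. IFITM1 was -0.15 with normexp, CAVIN3 -0.49 as the mean of all its probes, PIK3R5 -0.40 with repeat-run probes removed and the ribosomal list -0.039 with quantile normalization and -0.0086 with saturated genes removed, a setting that left 18 of its 74 genes and gave no value for RPS27, RPL7, ALDOA and CEBPA. Median scaling moved the median of all genes from -0.02 to 0.18, so the interferon list, with a mean of 0.078, passed as lower than other genes (adjusted p = 0.027). The cause was not tested for the other values.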

Other observations

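The tests of D816V array 3 on repeat-run probes, of the range within the slide, and of the splits by gene counts were chosen only after the result was seen. The comparison of ribosomal genes saturated on no array was added after the list's result was seen and before its own value was computed; the other tests in this part were chosen before their result was seen.

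Apart from HMOX1, genes named in this paragraph fall outside the rule and were chosen after their values were seen. With wild-type array 1 and D816V array 3 left out, a choice made after seeing the data, limma called 70 genes, 69 of them higher with D816V c-Kit, and 41 of the 70 were read by probes with a run of 8 or more alternating G and A. Of the 29 others, 5 were still called when such probes were also removed: HMOX1 (log2 fold change 3.90, SE 0.19), the interferon-stimulated genes IFI44 (3.82, SE 0.25) and OAS3 (2.83, SE 0.17), the serine protease HTRA3 (3.74, SE 0.17) and the pseudogene TMED10P1 (2.88, SE 0.18). The other 24 kept their log2 fold changes, with a median size of 2.57 and a median SE of 0.22 before and after, and their adjusted p rose from between 0.022 and 0.048 to between 0.058 and 0.11, because the adjustment no longer held the small p-values of the removed probes. These 4 arrays were kept because the other arrays stood apart, so the counts describe these arrays and are not a test of the receptor.

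Probes with long runs of alternating G and A read higher on D816V arrays 1 and 2. Over 117 such probes with a run of 8 or more, the median deviation was 1.04 and 1.47 there, against -0.06, -0.53 and -1.07 on the wild-type arrays. D816V array 3 stood at -1.01, but 1 array excludes nothing, so a response of the D816V cultures stays open. Base composition is argued against by matched probes without a run, whose median log2 fold change was 0.051 against 1.16 with it. In 41 genes that also had a probe without a long run, the other probes had a median of -0.061 against 0.40. This is consistent with binding through the repeat itself, as a hypothesis; what carried the repeat in those samples stays open.

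Interferon-stimulated genes stood apart on wild-type array 1, with a median deviation of 2.54. A slide effect acting through brightness and GC content is argued against, since that median lay at percentile 100 of 10000 random lists matched on both. A second list of 27 tested interferon-inducible genes, sharing no member with the first, had a median of 1.19 on that array and at most 0.08 on the others, which is consistent with an interferon response in that sample. The slide cannot give the range of 1.76 in the first list over the 5 arrays that share a slide, but for wild-type array 1 slide and sample cannot be told apart, because it was alone on its slide.

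The 4 lists past camera's threshold were set against 10000 random lists of equal signal, since dim genes had lower fold changes. The means of cholesterol synthesis and of heat shock lay at percentile 100 and that of MHC class II at percentile 0.02. Their matched lists had medians of 0.02, 0.05 and -0.04, so a trend with signal does not give these means. The percentiles are not further evidence of a shift. These lists had already passed camera, and the random lists did not keep the correlation between genes of a list. The ribosomal list lay at percentile 0: its mean of 0.13 was below the median of 0.22 of its matched lists. This met the bound set beforehand against the trend, but on the low side. It therefore does not argue against the trend as a source of the positive mean. It decides nothing further, because 56 of its 74 genes were saturated on at least 1 array. Over the 139 tested genes saturated on all 6 arrays the mean log2 fold change was 0.21. The log2 75th percentile subtracted from each array was on average 0.21 higher with wild-type c-Kit. The 18 ribosomal genes saturated on no array had a mean of -0.0086 against 0.13 for the list, which is consistent with saturation as the source of that call; whether the saturated genes changed was not measured. For the other lists the receptor, SCF, serum and chance remain open, since all 10 splits of the arrays, given below, called at least 4 lists. For 2 of them single arrays remain open too. The heat shock call ended without wild-type replicate 2 (mean 0.12). MHC class II stood at 0.59 on wild-type array 1, alone on its slide, and at -0.49 on D816V array 3. Its mean was -0.18 within the slide of 5 arrays and -0.025 without both arrays.

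With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. For genes called the real count was 0 and the highest other 3; every split gives at least 0, so the 10 of 10 that did so test nothing. For genes at unadjusted p under 0.05, 4 of the 10 splits gave at least the real 623, and the highest other was 3379. That split set wild-type arrays 1 and 3 and D816V array 3 against the rest, and so follows neither the receptor nor the slide. It was the highest of the 10, and what sets these arrays apart was not tested. For lists past camera's threshold with the preset correlation, 10 of the 10 splits gave at least the real 4, and the highest other was 14.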
